A study of Mus musculus with 16 samples.

How the data were processed

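RNA sequencing compared E14Tg2A mouse embryonic stem cells grown with 0, 100, 150 or 200 µM NiCl2 for 4 or 6 days. Per the labels, libraries were made with the TruSeq Stranded mRNA kit, and each of the 8 groups had 2 replicates, 16 libraries in all. The replicate letters were not tied to values here, because the tables give 1 value per group.

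The deposited data used were 6 tables, 1 per dose and day, each with 26239 genes. Per the file headers, the authors gave for each gene its RefSeq identifiers and position, an RPKM (reads per kilobase of transcript, scaled to library depth) for the control and for the nickel group, a log2 fold change, a p-value and an adjusted p-value. Per the submitters' processing notes, STAR, DESeq2 and GRCm38 were used, and their versions and settings are not given in the sources used here. Coordinates in the text are those of the authors' tables, with the start counted from 1. Over genes with a mean count of at least 50, the median difference between the authors' log2 fold change and the log2 ratio of their RPKM values lay between 0.006 and 0.088 per table. Single genes depart from that median, and no ratio exists where a group is listed at 0. Genes with a log2 fold change of 0 and a p-value of 1 were counted as untested, and an adjusted p-value of 1 was taken as given where the authors' tool adjusted none. The authors' own subsets by adjusted p-value held the same genes as the calls made here.

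The plan written before the data were examined provided for this case: with only the authors' results at hand, their adjusted p-values were counted at 0.05 and no new test per gene was made. A standard error was implied by each log2 fold change and p-value, taking the ratio of the fold change to its error as normal. The samples, the tests, the alternatives not named below as added, 35 gene lists and the rule for named genes were also fixed before the data were examined. That rule took, per comparison, the 8 largest rises and 8 largest falls among genes with an adjusted p under 0.05 and a mean count of at least 50, skipping symbols of predicted genes. It added up to 4 members of each list past the threshold, up to 2 that did not pass where the list passed, and 14 genes read in every comparison. The text gives a part of the genes so chosen. Day differences were named for up to 5 genes in each direction and dose.

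Library depth was recovered from the authors' RPKM values. In a group of 2 libraries the mean RPKM of a gene moves in steps set by its length and both depths. Depths were searched that put the low values of 2056 single-exon genes on such steps, within 0.8%. Between 99.4 and 100.0% of the values used then lay on the steps, against 17.0 to 24.4% by chance. The depths in megareads, lower and higher library, were 43.2 and 51.1 for the day 4 control, 50.7 and 55.8 at 100 µM, 45.1 and 53.0 at 150 µM, and 47.4 and 57.1 at 200 µM. On day 6 they were 58.8 and 70.8 for the control, 60.6 and 76.2 at 100 µM, 34.1 and 61.0 at 150 µM, and 61.3 and 76.8 at 200 µM. The rule for choosing among depths was revised after the result for 150 µM on day 6 was seen, and the other groups moved little. Depths could not be tied to a replicate letter. Mean counts were estimated as RPKM times exonic length (GENCODE mouse M21) times mean depth for 24956 genes with a length. RPKM times length summed to 1.44 to 1.52 times what a complete RPKM scale gives, so these counts are too high by up to about that factor. The median implied standard error of log2 fold changes at a mean count of at least 50 ran from 0.124 at 100 µM on day 6 to 0.185 at 200 µM on day 4.

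Gene lists were tested with limma's camera on the signed test statistic (cameraPR, preset inter-gene correlation 0.01), with Benjamini-Hochberg adjustment over the lists of a comparison. An estimated correlation needs values per library, so a preset correlation of 0.05 was used as the alternative. Members past the threshold were counted over all genes tested and adjusted over the list alone. The difference between days was tested with a two-sided z test of the difference of both log2 fold changes, adjusted by Benjamini-Hochberg. The test was conservative: 560, 591 and 369 genes had an unadjusted p under 0.05 at 100, 150 and 200 µM, where 937, 939 and 944 would by chance. Overlaps between days used one-sided Fisher's exact tests over genes tested in both. Overlaps between doses of a day were set beside independent lists and beside 100 simulated pairs of unchanged groups that shared control libraries, with error correlation 0.5. Intervals of shares are 95% Clopper-Pearson intervals, and those of medians come from 10000 bootstrap draws. Both treat genes as independent. Genes whose span overlaps another gene on the same strand, 2602 in all, and genes with near-identical copies are reported as uncertain.

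The computations were tested on simulated data. With effects of 1, 2 and 3 on the log2 scale given to a part of the 11468 genes with a control RPKM over 1, the day test recovered 78.5, 96.0 and 98.3% at 100 µM, 71.2, 88.5 and 95.0% at 150 µM, and 73.9, 96.7 and 100.0% at 200 µM. Of its calls 5.7, 4.4 and 3.7% were false. The list test, simulated for 200 µM on day 6 with 20081 genes, found a moved list in 16 of 20 draws and called 0 of 680 other lists. The simulated genes were independent of each other, so these counts do not cover lists whose members vary together. The depth search returned the depths of 4 simulated pairs with an error of at most 0.2%.

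The alternatives were an adjusted p of 0.01, a log2 fold change of at least 1, a mean count of at least 50, Benjamini-Hochberg over every gene with a p-value, Bonferroni, other gene sets for the dose trend, and 4 other settings of the list test. Calls without overlapping genes and a dose trend over the genes of the other day were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1 were used.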

Results

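E14Tg2A cells, a mouse embryonic stem cell line, were grown in serum medium with LIF, the cytokine that keeps such cells undifferentiated. They received 0, 100, 150 or 200 µM NiCl2, a soluble nickel salt, which was renewed at each passage, every 2 days. RNA was taken on day 4 and on day 6, and 2 sequencing libraries were made per dose and day, giving 8 groups and 16 libraries. The series title frames the question as whether nickel undoes the epigenetic repression of developmental genes. Each dose was set against untreated cells of the same day, in 6 comparisons. All RPKM values, log2 fold changes and adjusted p-values of single genes come from the authors' deposited tables, which hold 1 RPKM per group and no value per library. The error after a log2 fold change is the standard error implied by the authors' p-value. Nothing in the labels says that the replicates came from separate cultures, so the p-values may measure technical spread only. Steps in the RPKM of 2056 single-exon genes placed the library depths between 34.1 and 76.8 megareads (M reads).

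Nickel changed 200 genes at 100 µM, 1315 at 150 µM and 1542 at 200 µM on day 4 (adjusted p under 0.05 in the authors' deposited tables). On day 6 the counts were 567, 861 and 1901 genes. Such counts depend on the error of each comparison as well as on the size of effects. At a mean count of at least 50 the median implied standard error was 0.169, 0.148 and 0.185 with rising dose on day 4. On day 6 it was 0.124, 0.172 and 0.17. At a log2 fold change of at least 1 the counts were 75, 309 and 511 on day 4 and 93, 254 and 695 on day 6. Higher and lower genes numbered 111 and 89, 669 and 646, and 807 and 735 with rising dose on day 4, and 324 and 243, 467 and 394, and 1002 and 899 on day 6. In all 6 comparisons 42 genes were higher and 40 were lower than in control cells. The 42 included Nanog and Klf4, which encode pluripotency factors, Tdgf1, the glucose transporter genes Slc2a1 and Slc2a3, the lactate transporter gene Slc16a3, the chaperone genes Hspa5 and Calr, and the 2-cell stage genes Tmem92 and Arg2. The 40 included Atf4, which encodes a transcription factor of the amino acid response, Chac1, Pck2, Mthfd2, Slc3a2, and the Nodal inhibitor genes Lefty1 and Lefty2. These examples were chosen after their values were seen.

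**Figure D1:**
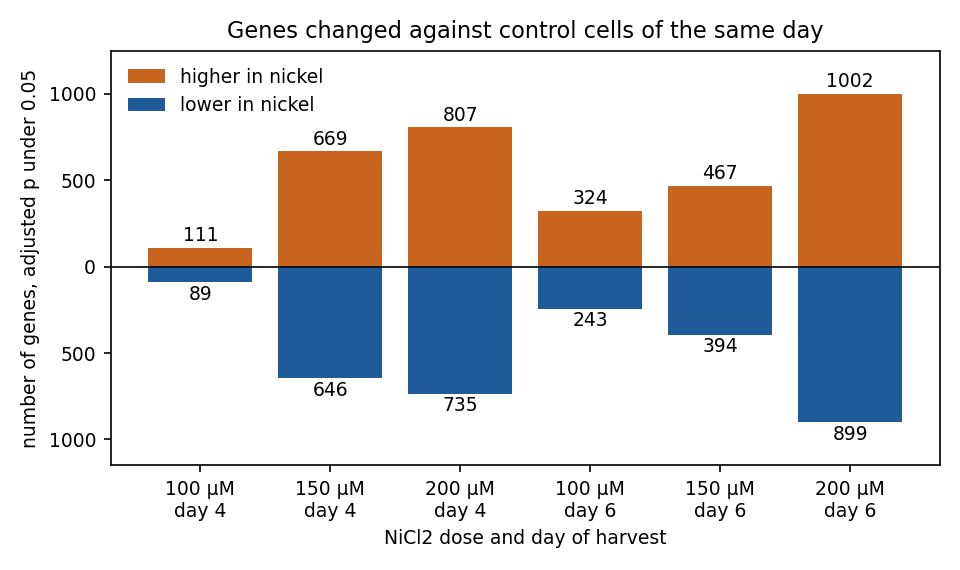
Number of genes higher (upward bars) or lower (downward bars) in nickel-treated than in control cells of the same day, for each dose and day, at an adjusted p under 0.05 in the authors' deposited tables. The counts run from 111 higher and 89 lower at 100 µM on day 4 to 1002 higher and 899 lower at 200 µM on day 6.

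At 100 µM on day 4, genes of the 2-cell embryo were higher and targets of ATF4 were lower. Of 22 tested genes of the 2-cell-like state, a rare condition of embryonic stem cells that resembles the 2-cell embryo, 15 rose (15 adjusted over the list alone) and none fell. The authors' deposited table gave Zfp352 an RPKM of 0.416 in control and 1.97 in nickel (log2 fold change 2.28 ± 0.48, adjusted p = 0.00042), and Tmem92 0.856 and 3.5 (2.06 ± 0.38, adjusted p = 2.5e-05). Of 34 ATF4 target and amino acid response genes, 8 fell (18 adjusted over the list alone). They were led by Chac1, which encodes a glutathione-degrading enzyme, from RPKM 17.6 to 4.74, and by Nupr1, from 27.7 to 11.5, in the authors' deposited table (log2 fold changes -1.85 ± 0.22 and -1.23 ± 0.23). Nanog, at chromosome 6:122707565-122714633, was 1.43-fold higher at RPKM 243 against 168 in the authors' deposited table (0.51 ± 0.07, adjusted p = 5.4e-12). Among 28 core and naive pluripotency genes 6 rose, Dppa2, Fbxo15 and Tdgf1 among them, and none fell (8 up and 2 down adjusted over the list alone).

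Limma's camera test compared each of 35 gene lists with all other genes. Its calls depended on the statistic. With the log2 fold change of genes with a mean count of at least 50, 19 list results of the 6 comparisons were kept, 44 lost and 1 reversed. At 100 µM on day 4 the 2-cell-like list (adjusted p = 2.82e-77), the naive list (1.81e-11) and the hypoxia list (1.62e-06) rose, and the ATF4 list fell (adjusted p = 7.13e-27). Of 48 genes responsive to hypoxia and its factor HIF, 5 rose and 1 fell (9 and 2 adjusted over the list alone). In the authors' deposited table Slc16a3 went up 1.58-fold and Slc2a1 1.43-fold, while Ndrg1 went down 1.97-fold. Smaller rises covered heat shock genes (2 of 23 up; 4 up and 1 down adjusted over the list alone, adjusted p = 0.000568) and endoplasmic reticulum chaperones (2 up, 1 down of 22; 3 and 1 adjusted over the list alone, adjusted p = 0.00241). Cholesterol synthesis genes rose as a list with 0 members called, also when adjusted over the list alone (adjusted p = 0.00135). Of 21 H3K9 methylation and retroelement repression genes, 1 was called up, Trim28, a corepressor gene (2 adjusted over the list alone, adjusted p = 0.00284). WNT targets (1 up, Lef1; 2 adjusted over the list alone, adjusted p = 0.0201) and nuclear oxidative phosphorylation genes (0 called either way; adjusted p = 0.0392) also rose. Germline genes repressed by DNA methylation fell with 0 called either way (adjusted p = 0.0235). These last 3 gave adjusted p = 0.107, 0.333 and 0.201 at a preset correlation of 0.05, in that order. The primed pluripotency list did not pass (adjusted p = 0.552), with a median log2 fold change of 0.1 over 18 members while its test pointed down. Zscan4, Usp17l and Pramel genes have near-identical copies, so their single values are uncertain. Only 8 members of the 2-cell-like list have no second copy of their name in it. Copies that share reads are not separate evidence, so the member counts and camera p-values of this list may be too strong in all 6 comparisons. At a preset correlation of 0.05 the camera test gave this list adjusted p = 6.49e-46 at 100 µM on day 4.

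**Figure D2:**
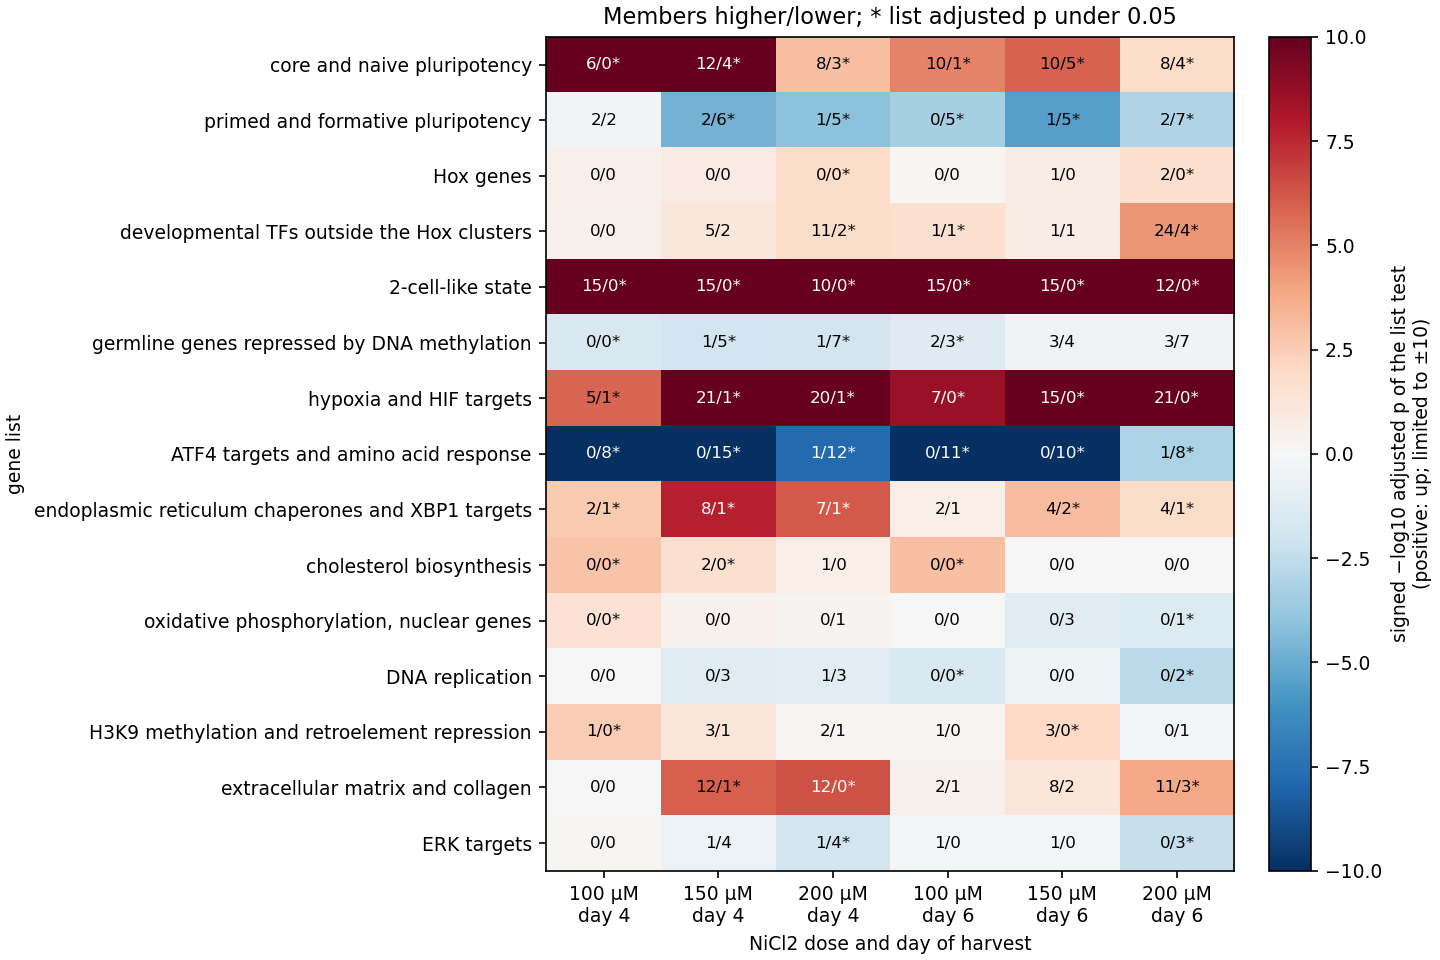
Gene lists that passed in at least 2 comparisons, by dose and day. Cells give the members called higher/lower, an asterisk marks an adjusted p under 0.05, and colour shows the signed -log10 adjusted p of the list test, limited to 10 either way. The 2-cell-like state and hypoxia lists were up and the ATF4 list was down in all 6 comparisons.

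At 150 µM on day 4, hypoxia targets, extracellular matrix genes and endoplasmic reticulum chaperones rose, and ATF4 targets and genes of the primed state fell. Of 48 hypoxia genes 21 rose and 1 fell (24 and 3 adjusted over the list alone, adjusted p = 5.64e-27). The authors' deposited table listed Slc16a3 at RPKM 27.1 in control and 51 in nickel (log2 fold change 0.95 ± 0.08) and Egln3, a HIF prolyl hydroxylase gene, at 8.36 and 15.2 (0.9 ± 0.14). Slc2a1, at chromosome 4:119108745-119137329, reached RPKM 300 from 177 in the authors' deposited table (0.8 ± 0.05, adjusted p = 3.4e-47). Among 36 tested extracellular matrix genes 12 rose and 1 fell (13 and 2 adjusted over the list alone, adjusted p = 1.15e-06), led by P4ha2 and Plod2, which encode collagen hydroxylases, at 1.62- and 1.49-fold in the authors' deposited table. Chaperone genes rose 8 to 1 of 22 (9 and 1 adjusted over the list alone, adjusted p = 1.6e-08), with Hspa5 up 1.45-fold and Herpud1 down 2.27-fold in the authors' deposited table.

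The ATF4 list had 15 of 34 members down and 0 up (20 and 1 adjusted over the list alone, adjusted p = 3.23e-23), with Chac1 at RPKM 3.4 against 17.6 in the authors' deposited table. Naive genes rose 12 to 4 of 28 (14 and 4 adjusted over the list alone, adjusted p = 9.94e-16): Nanog was 1.69-fold and Tet2 1.54-fold higher in the authors' deposited table. Primed and formative genes fell 6 to 2 of 20 (7 and 3 adjusted over the list alone, adjusted p = 1.94e-05). Lefty1 dropped 1.96-fold and Lefty2 1.89-fold in the authors' deposited table, whereas the WNT effector gene Lef1 rose 2.04-fold. The 2-cell-like list had 15 of 22 up (17 adjusted over the list alone, adjusted p = 1.38e-37). Among 23 histone demethylases of the JmjC family, which are iron-dependent, 4 rose and 1 fell (6 and 2 adjusted over the list alone, adjusted p = 0.00918, and 0.0832 at a preset correlation of 0.05). With the log2 fold change of genes with a mean count of at least 50 as statistic, this list pointed down (adjusted p = 0.935). In that setting 4 lists passed at 150 µM on day 4, against 10 in the main test. Kdm3a was 1.25-fold and Kdm5b 1.24-fold higher in the authors' deposited table. Germline genes fell 5 to 1 of 36 (7 and 1 adjusted over the list alone, adjusted p = 0.0121, and 0.149 at a preset correlation of 0.05), with Stra8, a meiotic entry gene, up 2.75-fold against them in the authors' deposited table. Cholesterol genes rose (2 of 26 up, 2 adjusted over the list alone, adjusted p = 0.0265, and 0.163 at a preset correlation of 0.05). Among the genes with the largest falls, Piwil4, which encodes a PIWI protein, went from RPKM 5.66 to 0.791 in the authors' deposited table (-2.82 ± 0.24).

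At 200 µM on day 4, developmental transcription factor genes rose as a list, in a call that was lost at a stricter preset correlation. Of 143 tested transcription factor genes of development outside the Hox clusters, 11 rose and 2 fell (10 and 2 adjusted over the list alone). Tlx1 and Isl1 were listed at 0 in control cells and at RPKM 0.263 and 0.132 in nickel in the authors' deposited table. Foxa1, an endoderm pioneer factor gene, rose from RPKM 0.118 to 0.829 and the heart and trophoblast gene Hand1 from 0.177 to 1.02 in the authors' deposited table (2.89 ± 0.81 and 2.59 ± 0.75). The list passed its test (adjusted p = 0.0152), as did 37 tested Hox genes with 0 members called either way, also when adjusted over the list alone (adjusted p = 0.0152). At a preset correlation of 0.05 they gave adjusted p = 0.277 and 0.172. Tlx1, Isl1, Foxa1 and Hand1 stayed low, at RPKM 1.02 or less in nickel.

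Hypoxia genes rose 20 to 1 of 48 (25 and 2 adjusted over the list alone, adjusted p = 1.64e-16), and Slc2a1 reached RPKM 362 from 177 in the authors' deposited table (1.1 ± 0.1). Matrix genes rose 12 to 0 of 36 (13 and 2 adjusted over the list alone, adjusted p = 4.58e-07) and chaperones 7 to 1 of 22 (11 and 1 adjusted over the list alone, adjusted p = 7.16e-07). The 2-cell-like list had 10 of 22 up (13 adjusted over the list alone, adjusted p = 9.87e-12) and the naive list 8 up and 3 down of 28 (9 and 5 adjusted over the list alone, adjusted p = 0.00103). In that list Nanog was 1.84-fold and Fgf4 1.69-fold higher, and Klf5, a target of LIF signalling, 1.86-fold lower in the authors' deposited table. ATF4 targets fell 12 to 1 of 34 (14 and 1 adjusted over the list alone, adjusted p = 1.66e-08) and primed genes 5 to 1 of 20 (6 and 2 adjusted over the list alone, adjusted p = 7.71e-05). The immediate early genes Fos and Egr1 dropped 3.33- and 2.63-fold in the authors' deposited table, in an ERK target list with 4 down and 1 up of 20 (4 and 2 adjusted over the list alone, adjusted p = 0.0151, and 0.0976 at a preset correlation of 0.05). Germline genes fell 7 to 1 of 36 (8 and 4 adjusted over the list alone, adjusted p = 0.0159, and 0.172 at a preset correlation of 0.05), Dazl among them at RPKM 5.62 against 11.7 in the authors' deposited table. In the imprinted list, which did not pass, the noncoding RNA Kcnq1ot1 rose 4.05-fold, from RPKM 0.0406 to 0.158 in the authors' deposited table. Cdkn1c fell 1.61-fold in that table, and a link between both changes was not tested. The ribosomal protein gene Rps27 was listed at RPKM 14.2 against 706 and overlaps Rps27rt, so its change is uncertain.

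At 100 µM on day 6, the 2-cell-like and ATF4 groups again moved in opposite directions. In total 15 genes of 22 in the 2-cell-like list rose and 0 fell (19 up adjusted over the list alone, adjusted p = 7.52e-71). Sp110 was 3.45-fold and Zfp352 3.04-fold higher in the authors' deposited table (1.79 ± 0.5 and 1.61 ± 0.38). ATF4 targets fell 11 to 0 of 34 (20 down adjusted over the list alone, adjusted p = 9.35e-25), with Chac1 at RPKM 8.31 against 21 and Atf4 at 129 against 190 in the authors' deposited table. Naive genes rose 10 to 1 of 28 (12 and 3 adjusted over the list alone, adjusted p = 1.1e-05) and hypoxia genes 7 to 0 of 48 (14 and 1 adjusted over the list alone, adjusted p = 2.28e-09). Of 20 primed genes 5 fell and 0 rose (5 down and 3 up adjusted over the list alone, adjusted p = 0.000468). They included the de novo DNA methyltransferase gene Dnmt3b, 1.41-fold lower in the authors' deposited table (-0.49 ± 0.07, adjusted p = 1.5e-10).

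Smaller shifts were found for cholesterol genes (0 called, 2 up adjusted over the list alone, adjusted p = 0.0009) and for 13 mitochondrially encoded genes, of which mt-Cytb and mt-Nd4, which overlaps another gene and is uncertain, fell (2 down, 2 adjusted over the list alone, adjusted p = 0.00174). Developmental transcription factors rose with 1 up, Phox2a, and 1 down, Neurod1, of 148 (1 and 1 adjusted over the list alone, adjusted p = 0.0271, and 0.476 at a preset correlation of 0.05). DNA replication genes fell with 0 called (2 down and 1 up adjusted over the list alone, adjusted p = 0.0288, and 0.246 at a preset correlation of 0.05). Germline genes had 2 up and 3 down of 36 (2 and 3 adjusted over the list alone, adjusted p = 0.0493, and 0.332 at a preset correlation of 0.05). Rsc1a1, listed at RPKM 6.25 in control and 0.373 in nickel in the authors' deposited table, lies within Ddi2 on the same strand and is uncertain.

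At 150 µM on day 6, the naive and 2-cell-like genes rose and genes of the primed state fell. The 2-cell-like list had 15 of 22 up (15 adjusted over the list alone, adjusted p = 5.24e-54), with Arg2, an arginase gene, at RPKM 4.05 against 0.986 in the authors' deposited table (2.13 ± 0.39). Naive genes rose 10 to 5 of 28 (12 and 7 adjusted over the list alone, adjusted p = 1.2e-06), and Tet2, which encodes a 5-methylcytosine dioxygenase, was 1.87-fold higher in the authors' deposited table (0.9 ± 0.09). Primed genes fell 5 to 1 of 20 (7 and 3 adjusted over the list alone, adjusted p = 3.27e-06): Lefty1 went from RPKM 125 to 48.1 and Dnmt3a from 23.5 to 14.2 in the authors' deposited table. Hypoxia genes rose 15 to 0 of 48 (20 and 3 adjusted over the list alone, adjusted p = 1.2e-11), with Pfkfb3, a glycolysis regulator gene, up 1.85-fold in the authors' deposited table. ATF4 targets fell 10 to 0 of 34 (13 down adjusted over the list alone, adjusted p = 4.2e-11).

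Chaperone genes rose 4 to 2 of 22 (5 and 2 adjusted over the list alone, adjusted p = 0.00085). H3K9 methylation genes rose 3 to 0 of 21 (3 adjusted over the list alone, adjusted p = 0.0095, and 0.0806 at a preset correlation of 0.05). Targets of p53 fell 5 to 1 of 33 (6 and 2 adjusted over the list alone, adjusted p = 0.0468, and 0.261 at a preset correlation of 0.05), Cdkn1a, a cell cycle inhibitor gene, among them at 1.39-fold lower in the authors' deposited table. Pax6, an eye and brain factor gene, rose 2.36-fold in the authors' deposited table. Neither the Hox list (adjusted p = 0.184, 1 up, 1 adjusted over the list alone) nor that of other developmental factors passed (adjusted p = 0.188, 1 up and 1 down, 0 and 1 adjusted over the list alone). Alb, the albumin gene of liver, was listed at 0 in nickel and at RPKM 1.97 in control cells of day 6 in the authors' deposited table, and at 0 in all day 4 groups. This group held the shallowest library, at 34.1 M reads, beside one of 61.0 M reads.

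At 200 µM on day 6, developmental transcription factor genes rose, together with the hypoxia, matrix and 2-cell-like groups. Here 14 lists passed the main test, against 5 with the log2 fold change of genes with a mean count of at least 50 as statistic. Of 148 tested developmental factors outside the Hox clusters, 24 rose and 4 fell (27 and 4 adjusted over the list alone, adjusted p = 3.8e-05, and 0.0488 at a preset correlation of 0.05). Hand1 reached RPKM 0.928 from 0.139 and the organizer gene Gsc 0.985 from 0.218 in the authors' deposited table (2.78 ± 0.7 and 2.19 ± 0.68). Tbx18, Tbx5 and Mab21l2 were listed at 0 in control cells and at RPKM 0.131, 0.0582 and 0.1 in nickel in the authors' deposited table. Of 38 tested Hox genes 2 rose (2 adjusted over the list alone, adjusted p = 0.0227, and 0.182 at a preset correlation of 0.05). Among them Hoxd1, at chromosome 2:74762980-74765142, was 5.23-fold higher in the authors' deposited table (2.39 ± 0.77).

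Hypoxia genes rose 21 to 0 of 48 (25 and 1 adjusted over the list alone, adjusted p = 1.56e-16), with Pfkfb3 up 2.37-fold, Slc16a3 2.08-fold and Vegfa, the vascular growth factor gene, 1.45-fold in the authors' deposited table. Matrix genes rose 11 to 3 of 38 (12 and 4 adjusted over the list alone, adjusted p = 0.000176), among them P4ha2 and the basement membrane collagen gene Col4a1 at 2.05- and 1.77-fold in the authors' deposited table. The 2-cell-like list had 12 of 22 up (17 adjusted over the list alone, adjusted p = 5.82e-20), led by Sp110, Pramel16 and Usp17ld. Chaperones rose 4 to 1 of 22 (6 and 2 adjusted over the list alone, adjusted p = 0.0159, and 0.104 at a preset correlation of 0.05). Naive genes rose 8 to 4 of 28 (10 and 5 adjusted over the list alone, adjusted p = 0.0159, and 0.117 at a preset correlation of 0.05). Within them Prdm14 was 1.85-fold higher, and Gbx2 and Klf5 were 2.05- and 1.83-fold lower in the authors' deposited table.

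Gbx2 and Klf5 also belong to the LIF and STAT3 targets, which fell 6 to 1 of 17 (7 and 1 adjusted over the list alone, adjusted p = 0.00102). Primed genes fell 7 to 2 of 20 (7 and 3 adjusted over the list alone, adjusted p = 0.00102), with Lefty1 down 3.2-fold and Dnmt3b down 2.02-fold in the authors' deposited table. ATF4 targets fell 8 to 1 of 34 (11 and 1 adjusted over the list alone, adjusted p = 0.000705). Also lower were ERK targets (3 of 20 down; 8 adjusted over the list alone, adjusted p = 0.00461) and DNA replication genes (2 of 33 down; 2 adjusted over the list alone, adjusted p = 0.00202). Genes of G2 and mitosis fell (5 of 30 down; 8 adjusted over the list alone, adjusted p = 0.0045, and 0.0642 at a preset correlation of 0.05), including the mitotic kinase gene Plk1, 1.35-fold lower in the authors' deposited table. Nuclear oxidative phosphorylation genes fell with 1 of 71 called (1 adjusted over the list alone, adjusted p = 0.0446, and 0.317 at a preset correlation of 0.05). Piwil4 fell from RPKM 4.48 to 0.24 and Hnf4a, a liver and endoderm factor gene, from 2.14 to 0.207 in the authors' deposited table (-4.36 ± 0.28 and -3.35 ± 0.31). Among genes with a mean count of at least 50, Alb had the largest fall, from RPKM 1.97 to 0.0221 in the authors' deposited table, and 11 of 26 liver genes other than Alb and Serpina3k were listed at 0 in day 4 control cells but above 0 in those of day 6.

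Core factors, metal response genes and lineage markers were read in every group. Nanog was higher in all 6 comparisons, at log2 fold changes of 0.51, 0.76 and 0.88 with dose on day 4 and 0.44, 0.57 and 0.81 on day 6 in the authors' deposited tables. Klf4 rose in all 6 as well, by 0.25 at 100 µM on day 6 to 0.48 at 150 and 200 µM on day 4. Pou5f1 passed only at 150 µM on day 4, 0.2 ± 0.06 higher in the authors' deposited table, where Esrrb fell by -0.17 ± 0.05. This does not set 150 µM apart. On day 4 Pou5f1 was 0.21 ± 0.08 higher at 100 µM and 0.21 ± 0.1 at 200 µM, without passing. Esrrb was at -0.26 ± 0.09 at 200 µM on day 4, also without passing. Sox2, T, Gata6 and Cdx2 passed in no comparison. The metallothionein genes Mt1 and Mt2, which respond to zinc and cadmium, rose 1.42- and 1.5-fold at 200 µM on day 6 in the authors' deposited table. Hmox1, a heme oxygenase gene of oxidative stress, fell 1.25-fold at 150 µM on day 4 in the authors' deposited table and did not pass elsewhere.

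Of the 35 lists 13 passed in no comparison. Their counts at 200 µM on day 6 are given with those adjusted over the list alone, followed by the lowest adjusted p of the 6 comparisons. Markers of other cell types were the neurectoderm and neuron list (2 up and 4 down; 3 and 4; 0.189), primitive streak and mesoderm (5 and 2; 5 and 2; 0.0696), primitive and visceral endoderm (4 and 5; 4 and 7; 0.135), trophectoderm (4 and 3; 6 and 3; 0.189) and fibroblast and stroma (2 and 3; 2 and 3; 0.24). Chromatin lists were Polycomb complex subunits (5 and 1; 5 and 1; 0.307), DNA methylation and demethylation (4 and 4; 4 and 4; 0.417) and imprinted genes (4 and 6; 6 and 8; 0.172). Metal and stress lists were metallothionein and zinc transport (2 and 2; 2 and 3; 0.138), iron handling (1 and 0; 1 and 0; 0.276) and NRF2 targets (1 and 4; 1 and 6; 0.0594). The others were BMP and TGF-beta targets (3 and 3; 3 and 3; 0.0583) and the epithelial to mesenchymal transition (6 and 4; 7 and 4; 0.307). No list that passed had a median of the opposite sign to its test.

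Among genes changed at 200 µM, the median effect grew with dose on both days. Among the 1542 genes changed at 200 µM on day 4, the median size in the direction of that change was 0.26 at 100 µM, 0.45 at 150 µM and 0.71 at 200 µM on the log2 scale. In 85.3% of them the effect rose at each step of dose (95% Clopper-Pearson interval 83.4 to 87.0%), against 16.7% for a random order of 3 values. On day 6 the medians were 0.29, 0.45 and 0.75 over 1901 genes, and 64.9% rose at each step (62.7 to 67.0%). The log2 fold changes of Nanog, Slc2a1, Lefty1 and Hnf4a grew with dose on both days in the authors' deposited tables, whereas that of Chac1 was largest at 150 µM. The 1542 and 1901 genes were chosen for their change at 200 µM, which favours that order, and over the genes chosen on the other day the shares were 75.8% and 57.3%. Lists differed in this, by their median over members with a mean count of at least 50. With dose, the hypoxia list had 0.15, 0.25 and 0.35 on day 4 and 0.12, 0.23 and 0.34 on day 6. The 2-cell-like list had 1.88, 1.71 and 1.39, then 1.45, 1.79 and 1.89. The ATF4 list did not grow steadily, at -0.34, -0.33 and -0.25, then -0.25, -0.3 and -0.23.

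**Figure D3:**
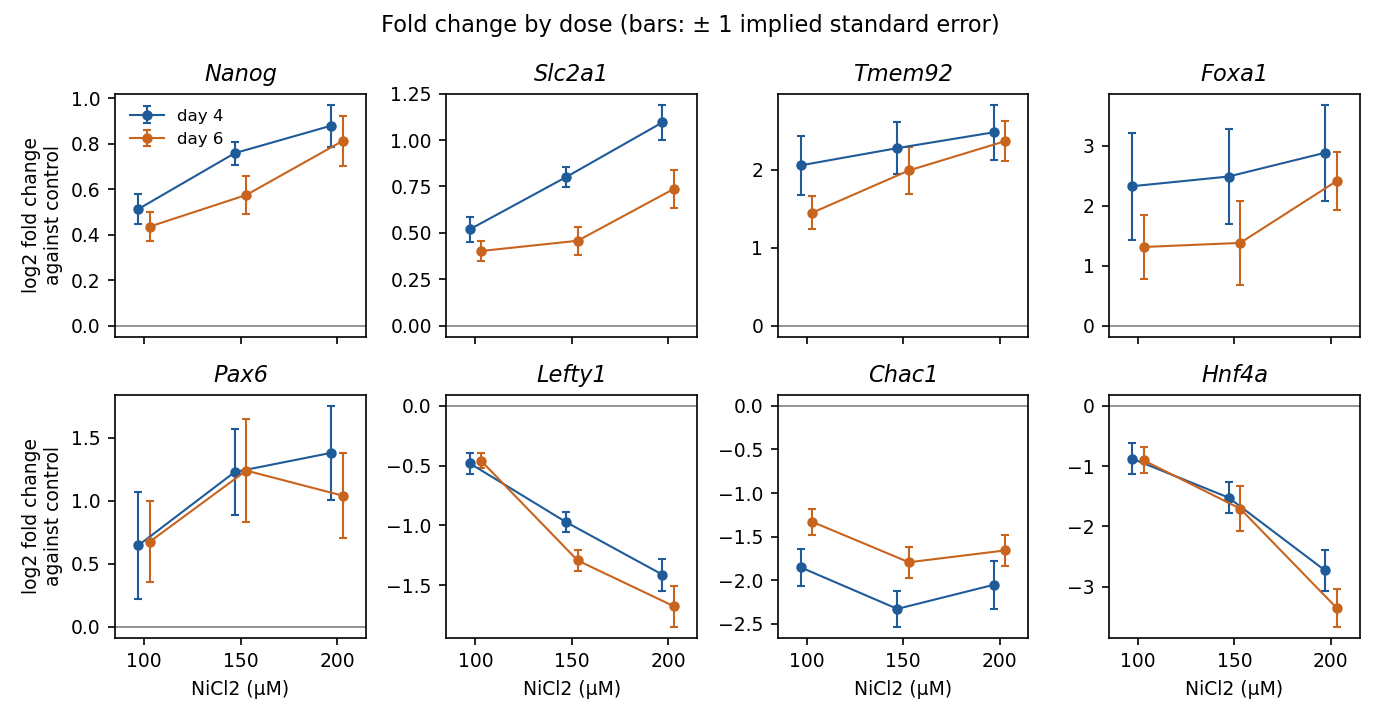
Log2 fold change against control cells of the same day for 8 genes at 100, 150 and 200 µM NiCl2 on day 4 (blue) and day 6 (orange), from the authors' deposited tables. Bars are 1 implied standard error each way, and vertical scales differ between genes. Nanog rises from 0.51 to 0.88 on day 4 and Lefty1 falls to -1.68 on day 6.

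Day 4 and day 6 shared many of their changed genes, and few genes passed a test of the difference between the days. At 200 µM 483 genes were higher and 458 lower on both days, against 42.7 and 34.8 for independent lists, and 1 gene moved in opposite directions (Fisher's exact test, one-sided; odds ratios 50.9 and 67.2; log10 p -445.2 and -460.0). At 150 µM the shared counts were 253 and 235 and at 100 µM 74 and 56, against 16.6 and 13.5 and 1.9 and 1.1. Log2 fold changes of the days correlated across genes at 0.37, 0.56 and 0.74 with rising dose, where genes are not independent replicates. A z test of the difference between days, with Benjamini-Hochberg adjustment, called 7 genes at 100 µM, 14 at 150 µM and 9 at 200 µM. The immediate early gene Fos was one of them: it was lower on day 4 and higher on day 6 at 150 µM in the authors' deposited tables (-1.07 and 1.32; difference 2.39 ± 0.41, adjusted p = 4.0e-05). At 200 µM Fos fell on both days. Nanog and Slc2a1 did not pass this test at any dose, with a difference for Slc2a1 of -0.34 ± 0.09 at 150 µM (adjusted p = 0.197). Without genes that overlap another on the same strand, 2, 8 and 1 genes were left. The z test was conservative: 560, 591 and 369 genes had an unadjusted p under 0.05, where 937, 939 and 944 would by chance. Few calls therefore do not show that effects were equal. Both tests treat the days as independent, and the sources used here do not say whether the days came from separate cultures.

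**Figure D4:**
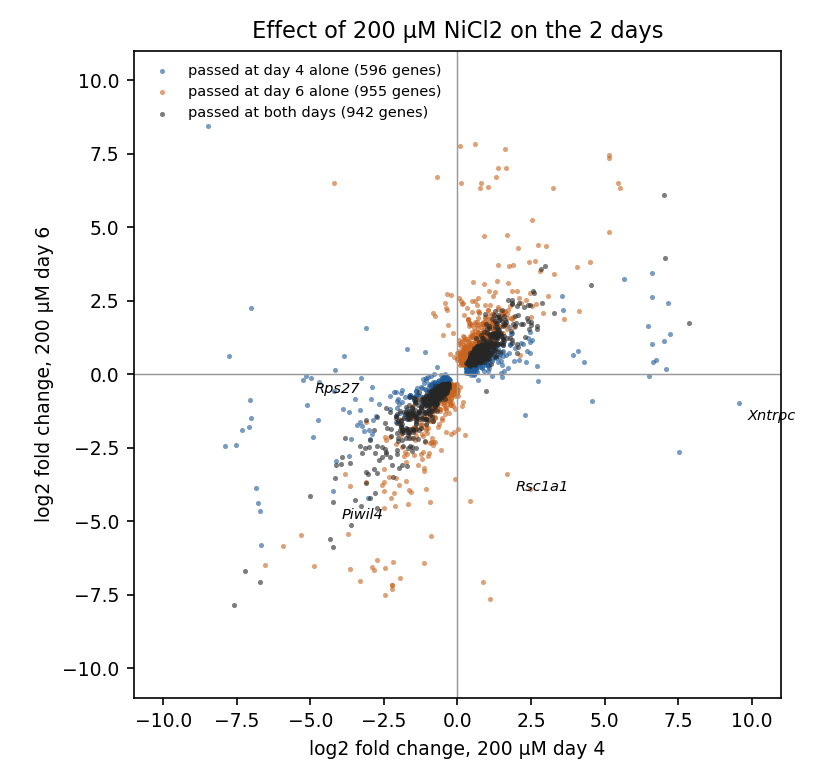
Log2 fold change at 200 µM on day 4 (horizontal) and day 6 (vertical) for genes that passed on day 4 alone (596, blue), day 6 alone (955, orange) or both days (942, dark), from the authors' deposited tables. Points on both days lie mostly at the lower left and upper right, and Rps27, Xntrpc and Rsc1a1, which overlap other genes, lie apart.

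Doses of the same day also shared their changed genes. On day 4, 105 genes were higher and 82 lower at both 100 and 150 µM, 67 and 75 at 100 and 200 µM, and 409 and 462 at 150 and 200 µM, against 3.9 and 3.0, 4.8 and 3.5, and 28.5 and 25.1 for independent lists. On day 6 the same pairs of doses shared 166 and 131, 221 and 185, and 280 and 269 genes, against 7.8 and 4.9, 16.6 and 11.2, and 24.0 and 18.2. The doses of a day used the same control libraries, and unchanged groups simulated with shared controls shared 0.0 genes on average. With every gene unchanged almost none is called, so this 0.0 does not measure how far shared controls raise the overlap. Correlations of log2 fold changes across genes were 0.75, 0.66 and 0.86 on day 4 and 0.65, 0.73 and 0.73 on day 6, beside 0.46 to 0.49 when simulated. The covariances were 0.1334, 0.1313 and 0.1954 on day 4 and 0.0927, 0.1187 and 0.1844 on day 6, beside simulated values of 0.0461, 0.052, 0.0461, 0.0411, 0.0359 and 0.048 in the same order. The control libraries could not be split, so part of the excess in shared genes may come from them.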

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

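The tests of explanations in this part were chosen after the results were seen, except that for liver RNA, and the splits by protocadherin cluster were added after the values over all pairs. The day difference test was planned.

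Fos, an immediate early gene, had a nickel effect that was higher on day 6 than on day 4 by 1.75 ± 0.39 on the log2 scale at 100 µM (adjusted p = 0.0272) and by 2.39 ± 0.41 at 150 µM. For the mitochondrial ribosomal RNA mt-Rnr2 the differences were 0.72 ± 0.12 and 1.36 ± 0.27, with RPKM 306 and 239 on day 4 and 210 and 275 on day 6 in control and 100 µM cells in the authors' deposited tables. At 150 µM the effect was lower on day 6 for Pcsk1n (-1.32 ± 0.3), Khdc3 (-0.74 ± 0.18) and Dusp9 (-0.5 ± 0.11). Sv2b, with a difference of 14.81, was listed at 0 in the nickel group of day 4 and in the control of day 6, so this size is no measure of fold.

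The other differences named here lie in genes that overlap another on the same strand. They were D7Ertd143e at 100 µM (0.71) and 150 µM (0.88), Epha4 at 150 µM (-0.73), Pcdhga5 at 150 µM (6.16) and 200 µM (4.69), Rsc1a1 at 100 µM (-4.34) and 200 µM (-5.09), and at 200 µM Moap1 (2.57), Xntrpc (-10.54), Rps27 (5.08) and Rps27rt (-1.21).

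Opposite calls of overlapping genes are the first pattern to weigh, with 25 gene pairs in 35 calls. At 200 µM on day 4 Rps27, at chromosome 3:90212667-90213648, went from RPKM 706 to 14.2 and Rps27rt from 701 to 1500 in the authors' deposited table, and their sum from 1410 to 1510. If nickel acted on each gene alike on both days, the direction would be the same. This was so in 48.6% of the 35 calls (95% interval 31.4 to 66.0%). The share was 37.5% of 16 calls, from 8 gene pairs, outside the protocadherin gamma cluster (15.2 to 64.6%) and 57.9% of 19 within it (33.5 to 79.7%). Outside the cluster this argues against an effect that held on both days as an account of all pairs, but not against an effect on a single day. Gm20605 with Lrch4 kept its direction at 150 and 200 µM, each dose being counted from both days. Within the cluster an effect on each gene stays open. Some pairs gave several calls, so these intervals are too narrow. Rps27 with Rps27rt counts as the same direction at a split of 0 on the other day. Reads moved between the genes of a pair stay open in both parts: the median absolute log2 change of the summed RPKM was 0.38 (0.18 to 0.98) over all calls, 0.24 (0.11 to 0.44) outside the cluster and 1.08 (0.35 to 2.18) within it, but RPKM is scaled by gene length, so a move between genes of different length changes the sum too.

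The second pattern is liver genes in day 6 control cells. Alb was at RPKM 1.97 in control and 1.89 at 100 µM, at 0 at 150 µM and 0.0221 at 200 µM on day 6, and at 0 in every day 4 group in the authors' deposited tables. RNA from liver cells, tested on 26 other liver genes with a list written before, is a candidate source: 17 of them (65.4%, 44.3 to 82.8%) were at 5% or more of the Alb level in day 6 control cells and above 200 µM cells. That count does not subtract the day 4 level: 9 of the 17 were at least 2-fold above day 4 control cells, 5 of these 9 being listed at 0 there, the rest were less than 2-fold above them or, for Ahsg, Cps1 and Kng1, not above them, and Sprr1a, outside the liver list, followed Alb on day 6 (RPKM 0.77, 0.631, 0 and 0.00824 with rising dose in the authors' deposited tables). Visceral endoderm formed in the culture stays open: 5 of 32 other endoderm genes (15.6%, 5.3 to 32.8%) were lower at 200 µM on day 6, but members with a high level in all groups would hide a small share, and a source in either control library could not be separated.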

How the results depend on the processing

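The dose trend over genes of the other day and the calls without overlapping genes were chosen after seeing the data; the other alternatives were planned. No paired analysis was possible because the tables give 1 value per group and no value per replicate. For the same reason edgeR and DESeq2 fits, TMM scaling, a low-count filter, leaving out a replicate, a fit of only 4 libraries, another pseudocount, a low-value filter and an estimated correlation were not run. In the order 100, 150 and 200 µM on day 4, then day 6, an adjusted p of 0.01 left 127, 769, 864, 299, 469 and 1047 genes, a log2 fold change of at least 1 left 75, 309, 511, 93, 254 and 695, and Bonferroni left 72, 318, 290, 133, 201 and 362, since each is stricter by construction. Benjamini-Hochberg over every gene with a p-value kept all 6 counts within 1.5 times, as did a mean count of at least 50 and leaving out overlapping genes. The share of genes rising with dose was 71.2% on day 4 and 53.9% on day 6 over genes changed at any dose, and 75.8% and 57.3% over genes of the other day; the cause was not tested. Genes that differed between days numbered 4 at 100 µM at an adjusted p of 0.01, 4 and 9 at 100 and 150 µM with a mean count of at least 50, and 2, 8 and 1 without overlapping genes, which removes tested genes by construction. Genes shared by 2 doses of a day at a log2 fold change of at least 1 numbered 65, 49 and 209 on day 4 and 65, 76 and 176 on day 6 for 100 and 150, 100 and 200, and 150 and 200 µM. Shared by both days were 39, 106 and 269 with rising dose. With the log2 fold change of genes with a mean count of at least 50 as statistic, 4, 4, 5, 4, 3 and 5 lists passed, and the cause was not tested. In that setting the JmjC demethylase list at 150 µM on day 4 reversed (adjusted p = 0.935). A preset correlation of 0.05 left 7 lists at 200 µM on day 4 and 9 on day 6, and ranks left 7 at 200 µM on day 4. Over single list results, that correlation kept 44 and lost 20, ranks kept 52 and lost 12, and a background of genes with a mean count of at least 50 kept 54 and lost 10, while the log2 fold change as statistic kept 19, lost 44 and reversed 1. Of the named gene results, Bonferroni kept 405 and lost 352, while Benjamini-Hochberg over every gene kept 729, lost 27 and gained 1. Depth may limit genes near RPKM 0 most, among them Hox and other developmental genes, but no comparison at matched depth was run.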

Other observations

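All tests of explanations in this part were chosen after the results were seen. Genes of DNA methylation moved in both directions, in a list that did not pass. Dnmt3a and Dnmt3b, the de novo methyltransferase genes, were 1.8- and 2.02-fold lower at 200 µM on day 6 in the authors' deposited table, where Tet2 was 1.73-fold higher. Zfp57, which encodes a protein that guards methylation at imprinted regions, was higher in all 6 comparisons, from 1.26-fold at 100 µM to 1.51-fold at 150 µM on day 6 in the authors' deposited tables. Among imprinted genes Impact was lower in all 6, by -0.42 ± 0.09 at 100 µM and -0.75 ± 0.11 at 200 µM on day 4 (log2, the authors' deposited tables). Cdkn1c fell 2.08- and 2.39-fold at 150 and 200 µM on day 6 in the authors' deposited tables.

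Tfrc, the transferrin receptor gene, was 1.26- and 1.44-fold higher at 150 and 200 µM on day 4 and 1.2-, 1.25- and 1.31-fold higher with rising dose on day 6 in the authors' deposited tables, in an iron list that did not pass. Of 33 Polycomb subunit genes, Bmi1 and Phc3 were among 5 that rose at 200 µM on day 6, at 1.77- and 1.66-fold in the authors' deposited table, and E2f6 fell 1.37-fold.

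The rise of 2-cell-like genes is the third pattern weighed. Reads shared between paralogs stay open: 6 of 8 members with no second copy of their name in the list rose at 200 µM on day 6 (95% interval of the share 34.9 to 96.8%), but a name does not show whether a gene has near-identical copies elsewhere. A shift of all genes by the authors' scaling is argued against: it would move the list and the other genes alike, and the median log2 fold change of the 22 tested members was 1.89 above that of 20059 other tested genes (1.57 to 2.04). An effect of nickel on these genes remains a hypothesis found and tested on the same data, and a change in the share of cells in the 2-cell-like state was not tested.

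A fall of most Polycomb subunit genes is argued against as the source of the rise in developmental genes. At 200 µM on day 6, 1 of 33 subunit genes (3.0%, 0.1 to 15.8%) was lower, and their median log2 fold change was 0.01. Loss of a single subunit stays open, and Polycomb protein and activity were not measured. Loss of DNA methylation at germline promoters was left open by 7 germline genes lower and 3 higher of 36 (70.0% lower, 34.8 to 93.3%) at 200 µM on day 6. The list rose in no comparison and fell in its test at 100, 150 and 200 µM on day 4 and at 100 µM on day 6, with adjusted p = 0.201, 0.149, 0.172 and 0.332 at a preset correlation of 0.05. A stabilised HIF response was not tested apart from the rise of the hypoxia list in 6 of 6 comparisons, which restates the pattern, and comparisons of a day share their controls.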
